A study of Homo sapiens with 4 samples.

How the data were processed

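RNA from A549 cells, a human lung adenocarcinoma line, was measured on 4 single-colour Affymetrix arrays of 54675 probe sets. Per the labels, 3 arrays hold RNA of cells given resveratrol, a plant polyphenol, for 48 h, and 1 array holds RNA of cells given the ethanol vehicle. The dose is 25 µM in the sample titles and the series design, while the extraction protocol prints the same figure with millimolar as its unit; the titles are followed here. The labels call the treated arrays replicates and do not say whether they came from separate cultures. The p-values per probe set therefore measure only the spread between these arrays, which may be technical.

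The authors deposited a matrix of intensity values for all probe sets, with MAS5 named in the submitters' processing notes. The version and the scaling target are not given in the sources used here. The values are linear, all above 0, and the array means lie between 705 and 715. A second deposited table gives the authors' own lists of genes with model-based intensity values and a signed fold, a score made by dChip per the file headers, for the 2950 probe sets in those lists. Its header names dChip and gives no version or normalization. The table holds 74 lists, of which 40 are gene ontology terms, 17 protein domains, 6 pathways and 11 chromosome regions. Of these probe sets 1096 have a higher and 1854 a lower fold in the authors' deposited table. Per the file headers, the ontology lists were found in a set of 4530 annotated genes picked from the array. Picked on the arrays analysed here, they are not independent evidence of any direction.

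Gene names came only from the LocusLink numbers in that table, matched to NCBI gene identifiers in a RefSeq gene table used for names alone. Of the 2950 probe sets, 2915 had 1 number and 35 several. A current symbol was found for 2899 probe sets, which name 1874 genes, and 16 with 1 number had no match. The other 51725 probe sets are unnamed here, so that a gene absent from the text may still be on the array. For the probe set with the number of CCNB2, the title in the table is that of a glutamate decarboxylase; it stays in the count of its list and no value is reported for CCNB2.

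The matrix values were kept as scaled by the authors. Values under the 25th percentile of all values (a signal of 38.99) were set to it, log2 was taken, and probe sets with a mean at or above the median of the means were kept. After removal of the 62 control probe sets, 27303 were tested. Resveratrol was compared with control with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The 2 residual degrees of freedom come from the 3 treated arrays, and the lone control array was assumed to vary like them. A change is the mean log2 value on the 3 resveratrol arrays minus the log2 value on the control array, and its SE is that of limma's moderated fit. A gene with several named probe sets was represented by the one of these with the highest mean. Unnamed probe sets of the same gene could not be considered.

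Gene groups fixed before the data were examined (39 lists) were tested with limma's camera at its preset inter-gene correlation of 0.01 where at least 3 genes were tested, which held for 20 lists. The background was the 1725 named genes tested, themselves a choice of the authors. The same test on the authors' lists (71 with at least 3 genes) was added after seeing the data. Camera with an estimated correlation, camera on ranks and fry, which asks whether the genes of a list move on balance one way, were alternatives. At the preset correlation camera sets the genes of a list against the other genes. Its p-values then rest on the spread between genes, not on that between arrays. With an estimated correlation camera uses the 2 residual degrees of freedom, on which few lists can pass, so a miss there decides little. Genes were named by a rule fixed before the data were examined. It took the 12 largest rises and 12 largest falls among named genes past the test and changed at least 2-fold on all 3 treated arrays, filled by the smallest change over the 3 arrays where fewer passed, up to 4 genes of each list, and 15 genes of prior interest, of which 9 were tested. Genes named outside this rule are marked as such. Some genes that the rule takes are not reported here.

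The procedure was tested on simulated data with the real means of 27303 probe sets and 200 changed ones, 5 times over. In the first version, spreads equal to the shrunken estimates of the treated arrays gave 15.9% false calls, above the 5% the threshold allows. A second version, written after that result, drew spreads from the prior that limma fits; 6.13% of calls were then false. In the second version 8.80% of probe sets changed by 0.5 on the log2 scale were recovered, 34.8% of those changed by 1, 62.4% at 1.5 and 71.6% at 2. Camera recovered 100% of lists shifted by 0.5 and called 1.14% of unshifted lists. Genes were drawn independently and lists at random, so correlation within a list was not tested. In both versions the control was drawn with the spread of the treated arrays, so that assumption was not tested either.

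Alternatives set before the data were examined covered the normalization (each array centred on its median, quantile), the filter (none, the mean of the group means, the 75th percentile), the floor (none, or log2 of the value plus 16), the variance model (no trend, robust), the threshold, the set test, each treated array left out, and removal of probe sets ending in _s_at, _x_at or _a_at. The authors' dChip values in place of the MAS5 signals were added after seeing the data. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. The number of arrays limits the precision, and there is a single control.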

Results

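Gene expression was measured in A549 cells, a line from a human lung adenocarcinoma, after 48 h with 25 µM resveratrol or with the ethanol vehicle. There were 3 resveratrol arrays and 1 control array. The study asked which genes resveratrol alters in these lung cancer cells, with p53 and TGF-beta/Smad signalling among its concerns. Median signals were 143 on the control array and between 141 and 145 on the resveratrol arrays. Over the tested probe sets, log2 signals correlated at 0.964 to 0.965 between the control and a resveratrol array and at 0.980 to 0.981 between resveratrol arrays; these correlations are across probe sets, which are not independent replicates. The 3′ to 5′ difference of GAPDH lay between -0.09 and 0.00 on the log2 scale on the 4 arrays. The 18S ribosomal RNA control probe sets were brighter on the control array, with a 3′ signal of 7319 against 1215 to 2065 on the resveratrol arrays and a 5′ signal of 18355 against 1162 to 6452, the last on replicate 1.

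With the low filter used here more probe sets passed the test upward than downward. Higher calls also led with the filter on the mean of the group means (66.2%) and at the 75th percentile (60.2%). Among the filter settings only the absence of a low filter turned the direction. Without a low filter 321 were higher and 1089 lower. Of those calls 840 had no spread between the resveratrol arrays, which the floor brings about by construction. The authors' own table has 1096 higher and 1854 lower folds, without a test, over its 2950 listed probe sets. On MAS5 signals 40.8% of the listed probe sets tested had positive changes. TRIM22, an interferon-inducible member of the tripartite motif family, rose from a signal of 90.5 to 443 ± 4.24 (SD, n = 3), a 4.90-fold change. ITGB4, the integrin beta 4 subunit of hemidesmosomes, rose 4.12-fold, and HNMT, which methylates histamine, rose 3.98-fold. The other 2 named probe sets of ITGB4 had log2 changes of 1.00 and 2.01. The authors' dChip values, brought in after the data had been seen, gave smaller log2 changes: 0.62 against 2.29 for TRIM22, 1.12 against 2.04 for ITGB4 and 0.29 against 1.99 for HNMT. CDKN1A, the p21 inhibitor of cyclin-dependent kinases, rose from 1564 to 5458 ± 64.4 (SD, n = 3), with a log2 change of 1.80 ± 0.07 (SE, adjusted p = 0.000168). H1-3, a replication-linked linker histone, fell by 1.98 ± 0.15 on the log2 scale (SE, adjusted p = 0.00142), from 1700 to 433 ± 32.2 (SD, n = 3). On dChip values the log2 change was 1.47 for CDKN1A, 1.71 for TM4SF20 and -0.44 for H1-3.

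In all, 1821 of 27303 probe sets passed the test, 1225 higher and 596 lower, and 418 of them changed at least 2-fold, 370 upward and 48 downward. By size alone, with no test, 362 probe sets differed from the control by at least 2-fold on each of the 3 resveratrol arrays, 329 upward and 33 downward. With a resveratrol array in the place of the control and the other 2 set against it, that count was 97 to 113 upward and 13 to 28 downward, from 2 arrays in place of 3. Among the genes that met the rule, the other large rises were TM4SF20 (3.66-fold), the muscle-type adenylosuccinate synthase ADSS1 (3.60-fold), PEAR1 (3.50-fold), MFGE8, a secreted glycoprotein that binds phosphatidylserine (3.47-fold), the EGF receptor ligand BTC (3.15-fold) and THBD, or thrombomodulin (3.03-fold). On dChip values the log2 changes were 0.51 for PEAR1, 0.43 for BTC, 1.02 for MFGE8, 0.98 for ADSS1 and 1.43 for THBD. For rises 64 genes met the rule, of which the 12 largest were taken. For falls only H1-3 and ACTN4 met it. ACTN4, an actin cross-linking protein, fell by 1.31 ± 0.17 on the log2 scale (SE). It was measured by a probe set built from an mRNA not marked as full length. Its other 2 named probe sets had changes of -0.65 and -0.53 (adjusted p = 0.27 and 0.206), not past the test. The dChip change was -0.44. The rule filled in 10 further falls by the smallest change on any of the 3 arrays, which is not the order of the mean changes, and 6 of these passed the test. CYP1B1, a cytochrome P450 induced through the aryl hydrocarbon receptor, fell by 0.99 ± 0.08 (SE). Its 3 named probe sets, picked by the authors on these arrays, all passed the test with changes between -1.14 and -0.89. The RNA-binding protein HNRNPR, the BMP receptor BMPR1B, H1-2, ZCCHC7 and SIM2 fell too, with log2 changes of -1.01, -1.04, -0.95, -1.05 and -0.94; on dChip values HNRNPR had -0.38 and SIM2 -0.62. Log2 changes that missed the threshold were -1.13 for SH3YL1, -1.06 for CAMKMT, -1.02 for HDAC8 and -0.86 for COL1A1. On dChip values these were -0.80, -0.77, -0.41 and -0.66. Probe sets without a name here held changes of up to 4.45 upward and -2.02 downward on the log2 scale.

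**Figure D1:**
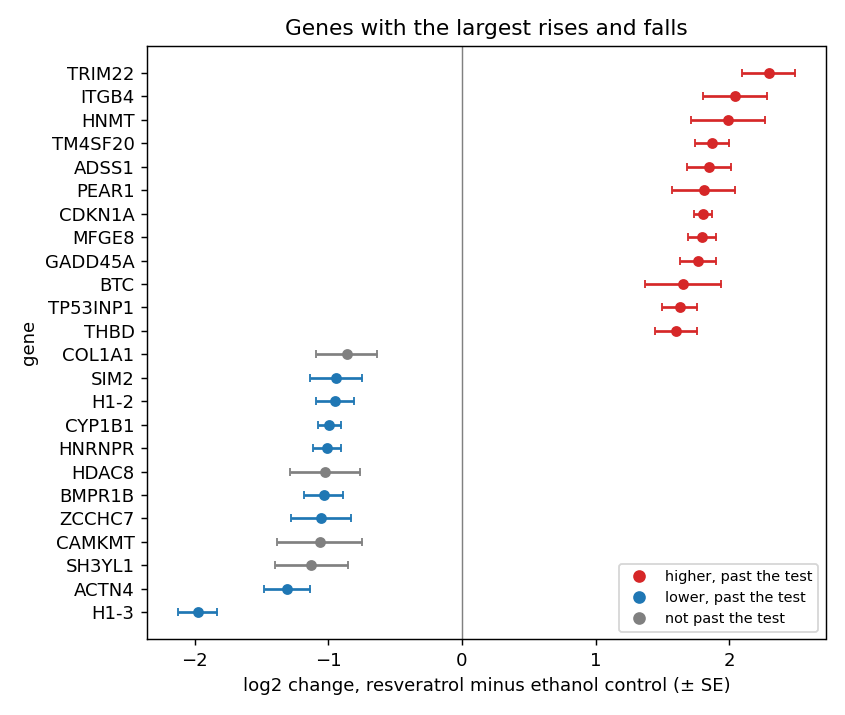
Log2 change (horizontal axis, resveratrol minus control, points with SE bars from the fit to 3 resveratrol arrays and 1 control array) of the genes picked by the rule for rises and falls (vertical axis). The 12 rises, taken from genes past the test, go from 1.60 for THBD to 2.29 for TRIM22, and grey points mark 4 falls not past it.

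These calls rest on pooling the spread by signal level and on a control that varies like the treated arrays. Without the intensity trend limma called 0 probe sets, with a smallest adjusted p of 0.0502 and 5370 at an unadjusted p under 0.05. In simulated data 6.13% to 15.9% of calls were false, depending on how the spread was drawn. The simulated control varied like the treated arrays, so that assumption was not tested there. On the authors' dChip values 10 of the 500 named genes past the test had the other sign, and 206, these included, had the other sign or a log2 change smaller by over 1.5 times.

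Of genes activated by the p53 transcription factor, 10 of 16 tested rose. Those named in this paragraph other than GADD45A, TP53INP1, SESN1, BAX and TNFRSF10B were named after their values were seen. The 16, out of 25 listed targets, are members with a tested probe set in the authors' lists, which were drawn up on these arrays. None fell, and all 16 changes were positive, with a median log2 change of 0.75; 14 rose when adjusted over the list alone. GADD45A, a growth arrest and DNA damage gene, rose 3.41-fold, TP53INP1 3.09-fold, the stress-response gene SESN1 2.77-fold and TP53I3 from 3209 to 7738 ± 88.5 (SD, n = 3). PPM1D, a phosphatase that dampens p53 signalling, rose 2.14-fold, BTG2 1.79-fold, the repair gene XPC 1.49-fold, CCNG1 1.46-fold and the pro-apoptotic BAX 1.40-fold. On dChip values 15 of the 16 changes were positive, with a median of 0.49. There 14 passed a test adjusted over the authors' listed probe sets alone, which cannot be compared with the count on MAS5 signals. The log2 change on dChip values was 0.77 for SESN1, 0.21 for BTG2, 0.0068 for MDM2 and -0.19 for ZMAT3. With MAS5 signals MDM2, ZMAT3, AEN, TNFRSF10B, SESN2 and POLH did not pass, with log2 changes from 0.35 to 0.76. A second, dimmer probe set of MDM2, the ligase that degrades p53, did pass (0.98, adjusted p = 0.033). The list was the only 1 of 20 past the camera test (adjusted p = 9.23e-07), a value that rests on the spread between genes. With an estimated correlation it did not pass (adjusted p = 0.597), nor did any other fixed list. That version rests on the 2 residual degrees of freedom, on which few lists can pass, so the miss decides little. Fry gave an adjusted p of 0.0174. On the same arrays the 18S ribosomal RNA signal was lower than on the control. Without probe sets ending in _s_at, _x_at or _a_at, where fewer probe sets were tested, 4 members passed the test. The list passed camera there with an adjusted p of 0.00212.

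**Figure D2:**
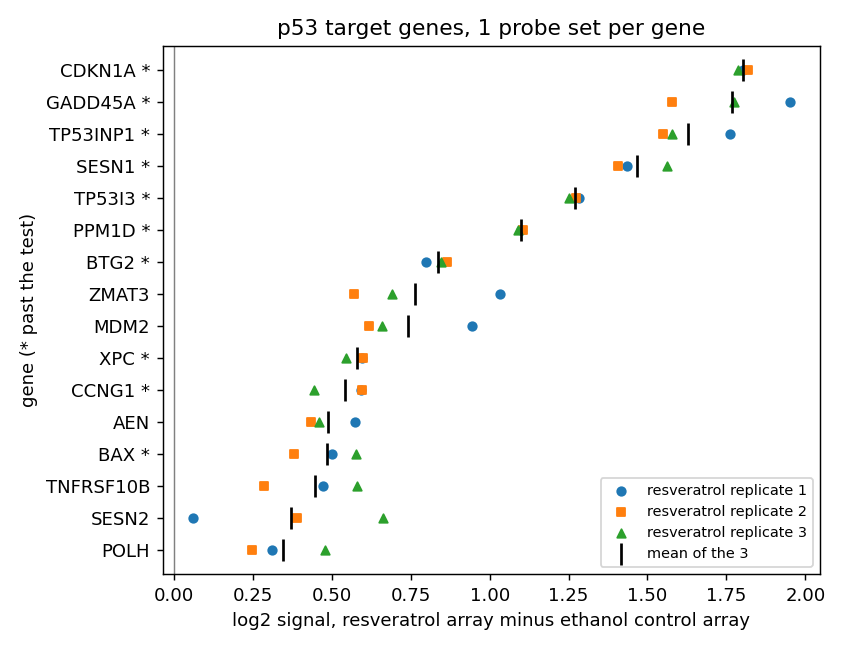
Log2 signal of each resveratrol array minus the control array (horizontal axis) for the 16 tested p53 targets (vertical axis, stars mark those past the test), with the mean of the 3 as a black bar. All arrays lie above 0 for all 16 genes, and CDKN1A has the highest mean at 1.80.

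Cell cycle genes changed in both directions. Tested were 11 of 27 listed genes of DNA replication and S phase and 8 of 25 listed mitosis genes. They were measured through probe sets that the authors listed on these arrays. Of all such probe sets tested, 40.8% had positive changes. Among the 11 replication genes, 5 rose and 1 fell. The G1/S cyclins CCNE2 and CCNE1 rose 2.14-fold and 1.62-fold, the replication licensing factor CDC6 1.36-fold, and the nucleotide synthesis genes RRM2 and TYMS 1.28-fold and 1.21-fold, while the helicase subunit MCM6 fell by 0.37 on the log2 scale. RRM2, TYMS and MCM6 were named after their values were seen. Of 8 tested mitosis genes 1 fell, the kinase PLK1, with a log2 change of -0.43 (adjusted p = 0.0498), and all 8 changes were negative; CCNA2 had a change of -0.27 and KIF11 of -0.32, neither past the test. None of the 4 tested genes of the fixed DNA repair list passed, the largest change being -0.31 for CHEK1, while of 48 genes in the authors' DNA repair list 9 rose and 7 fell. Among histone transcripts known to be polyadenylated, 4 of 6 rose, among them H2BC4 2.82-fold, H2BC21 1.77-fold and H2AJ 1.36-fold, and 1 fell, the linker histone H1-2. On dChip values the log2 changes were 0.53 for H2BC4, 0.15 for H2BC21 and 0.20 for H2AJ. The other named probe set of H2BC4 had a log2 change of 0.38 on MAS5 signals. By camera, adjusted p was 0.444 for the replication list, 0.194 for mitosis, 0.336 for repair and 0.22 for histones; fry gave 0.0319 for replication (upward) and 0.0268 for mitosis (downward).

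Of 28 listed TGF-beta and Smad pathway components 8 were tested, and of 20 listed target genes 9. Past the test were 1 component and 3 targets, against 500 of 1725 named genes in all. SMAD2, a receptor-activated transducer, fell by 0.35 ± 0.08 on the log2 scale (SE, adjusted p = 0.0434) and was the only 1 of 8 tested pathway components past the test. SMAD4 had a change of -0.23 (adjusted p = 0.217) and the inhibitory SMAD7 of 0.40 (adjusted p = 0.0895). Of 9 target genes 3 fell, ID1, ID2 and ID3, inhibitors of differentiation that BMP signals induce, with log2 changes of -0.47, -0.59 and -0.51. The list gives no expected direction for its members. ID1 was named after its value was seen. The targets ITGB6 and LTBP2 had changes of 1.09 and 0.74 that were not past the test, and ITGB6 had -0.04 on the authors' dChip values. Adjusted over each list alone, 1 component rose and 3 fell, and 4 targets rose and 4 fell. Camera gave an adjusted p of 0.22 for the components and 0.907 for the targets. The targets' median of 0.15 and mean of 0.11 are positive while the test pointed down.

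Lists for stress responses held rises and falls. NUPR1 and ATF3, both induced by amino acid and endoplasmic reticulum stress, rose 2.74-fold and 2.36-fold, and the serine synthesis enzyme PHGDH rose 1.35-fold, 3 of 7 tested in that list, while CEBPB, named after its value was seen, fell by 0.41. On dChip values ATF3 had a log2 change of 0.63, and its other named probe set had 0.72 on MAS5 signals against 1.24. Of 23 listed NRF2 targets 4 were tested, through probe sets that the authors listed on these arrays. All 4 had negative changes and 3 fell. These were GCLC, the catalytic subunit of glutamate-cysteine ligase, glutathione reductase GSR and malic enzyme ME1, with log2 changes of -0.52, -0.32 and -0.30. Neither list passed camera (adjusted p = 0.22 and 0.111). Both passed with fry (adjusted p = 0.0226 for each), the amino acid stress list upward and the NRF2 list downward. The NRF2 list also passed camera on ranks (adjusted p = 0.0289) and without probe sets ending in _s_at, _x_at or _a_at (0.0289). Neither list passed camera with an estimated correlation (adjusted p = 0.597 for each). The glucocorticoid- and stress-inducible phosphatase DUSP1 rose 1.35-fold, MYC fell by 0.49, and 2 of 4 immediate early genes rose. In the growth factor feedback list DUSP5 rose 1.84-fold and EGFR 1.35-fold, while the EGFR ligands AREG and EREG fell, with log2 changes of -0.53 and -0.48; EGFR was named after its value was seen. The interferon-stimulated genes OAS1 and RIGI rose 2.08-fold and 1.84-fold, 2 of 5 tested; the RIGI probe set ends in _x_at, and dChip gave log2 changes of 0.87 for OAS1 and 0.052 for RIGI. GREB1, an oestrogen-responsive gene, rose 2.86-fold as the only gene of its list tested, with a log2 change of 0.50 on dChip values against 1.51. The lipid synthesis regulator SREBF1 fell by 0.79 on the log2 scale. Of 4 tested actin cytoskeleton genes ACTA2 rose 2.15-fold, LIMA1 2.04-fold and PXN 1.41-fold, and ACTN4 fell; on dChip values the log2 changes of ACTA2, LIMA1 and PXN were 0.0044, 0.18 and 0.38. The basement membrane collagens COL4A1 and COL4A2 rose 1.41-fold and 1.36-fold. Of the other tested lists, 1 gene rose in each of pro-apoptotic (BAX of 6), anti-apoptotic (CFLAR), unfolded protein response (DNAJB9), heat shock (HSPA4L of 3), inflammatory (TNFAIP2 of 4) and glycolysis genes (HK1 of 2), and 0 of 3 hypoxia and 0 of 3 mesenchymal genes passed. The other 3 named probe sets of CFLAR had log2 changes between -0.07 and 0.34. NPC1 and CTSB rose among 7 autophagy and lysosome genes, and the mitochondrial regulator NRF1 fell by 0.73. GUSB and B2M, often used as reference genes, rose 1.40-fold and 1.21-fold. On dChip values the log2 changes were smaller by over 1.5 times for COL4A1 (0.30), CFLAR (0.23), DNAJB9 (0.28), HK1 (0.19), NPC1 (0.25), EGFR (0.18), GUSB (0.22) and NRF1 (-0.35). Of the fixed fibroblast marker list only COL1A1 was tested, and no member of the fixed leukocyte, endothelial, epithelial or sirtuin lists was.

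The authors' deposited gene lists, drawn up on these arrays and so no independent evidence, held 752 of 2648 tested probe sets past the test (28.4%; 438 higher, 314 lower), against 1069 of 24655 outside the lists (4.34%). Of 64 genes with an RNA recognition motif 20 fell and 3 rose, and of 42 in the mRNA processing pathway 8 fell, 0 rose and all 42 changes were negative, with a median of -0.31, while of 37 under RNA processing 3 fell and 3 rose (camera adjusted p = 0.0699). Examples, chosen like all genes of these lists after their values were seen unless named above, were HNRNPA2B1 and the poly(A) polymerase PAPOLA, which both fell with a log2 change of -0.48. Of 22 listed under translation initiation 9 fell and 0 rose, among them EIF4A1, EIF3B and the cap-binding EIF4E, with log2 changes of -0.63, -0.47 and -0.42; the actin regulator FMNL2, also in that list, fell by 0.52. Of 18 ubiquitin-specific proteases 4 fell, with a log2 change of -0.67 for USP16. On dChip values the changes were -0.39 for EIF4A1, -0.15 for EIF3B and -0.37 for USP16. Camera gave adjusted p values of 1.14e-05, 2.06e-05, 0.0071 and 0.0071 for the RNA recognition motif, mRNA processing, translation initiation and ubiquitin-specific protease lists. None of these passed with an estimated correlation (adjusted p = 0.366), a version that few lists can pass on 2 residual degrees of freedom. On the control array, from which these falls are measured, the 18S ribosomal RNA signal was also higher.

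In 5 further lists of the authors more genes rose than fell. Of 26 genes with a LIM zinc-binding domain 14 rose and 0 fell, among them TGFB1I1 (2.09-fold) and CSRP2 (2.03-fold). All 8 collagen-binding genes had positive changes and 5 rose, with the collagen chaperone SERPINH1 2.47-fold higher. Of 10 MHC class I receptor genes 6 rose, including MR1 (2.71-fold) and HLA-B (1.48-fold); the HLA-B probe set ends in _x_at and can match several class I genes. In glutathione metabolism 10 of 14 rose and 2 fell, with GPX3 2.13-fold and GPX1 1.95-fold higher. Of 38 genes with an EGF-like domain 14 rose and 7 fell. On dChip values the log2 changes were 0.63 for TGFB1I1, 0.64 for CSRP2, 0.54 for SERPINH1, 0.73 for MR1 and 0.27 for HLA-B. Camera gave adjusted p values of 0.00162, 0.00323, 0.0115, 0.00892 and 0.00892 for these 5 lists. Of 71 lists tested 29 passed, 15 higher and 14 lower, and 0 passed with an estimated correlation, where the 9 lists given here had an adjusted p = 0.366; fry called 53.

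**Figure D3:**
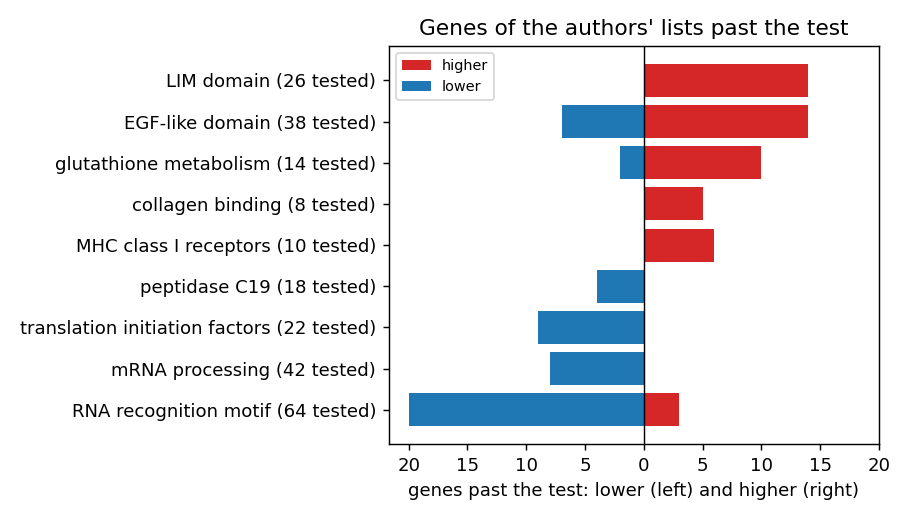
Number of genes past the test (horizontal axis, lower to the left and higher to the right of 0) in 9 of the authors' lists (vertical axis, with the number tested), from 3 resveratrol arrays and 1 control array. The RNA recognition motif list has 20 lower and 3 higher genes, and the LIM domain list 14 higher and 0 lower.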

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

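The dChip alternative and the set tests of the authors' lists were added after the data had been seen. Limits include the single control array, which cannot be left out, the variance model and signal near background. No paired analysis was possible because the control has 1 array, whose label carries no replicate number. Leaving out each resveratrol array in turn gave 1321 to 2172 changed probe sets (877 to 1383 higher, 419 to 789 lower), 426 to 457 changed 2-fold, 560 to 839 of the authors' probe sets, 21 to 26 of their lists, and 9 to 14 p53 targets higher, with camera's adjusted p for that list between 4.79e-13 and 3.41e-06. Without the intensity trend 0 probe sets passed (0 higher, 0 lower, 0 of the authors' probe sets and 0 p53 targets), with 5370 at an unadjusted p under 0.05. Without a low filter 321 were higher and 1089 lower, 989 changed 2-fold and 185 of the authors' probe sets passed; 840 of those 1410 calls had no spread between the resveratrol arrays, which the floor brings about by construction, and the share of higher calls was 22.8% in place of 67.3%. The 75th percentile filter tested fewer probe sets and gave 114 changed 2-fold and 15 of the authors' lists. An adjusted p under 0.01 gave 456 probe sets and a 2-fold minimum 418. Without probe sets ending in _s_at, _x_at or _a_at, fewer were tested and 946 passed (679 higher, 267 lower), with 236 changed 2-fold, 348 of the authors' probe sets, 11 of their lists, 2 fixed lists and 4 p53 targets. An estimated correlation left 0 fixed and 0 of the authors' lists (p53 targets 0.597), ranks gave 2 fixed lists (p53 and NRF2 targets), and fry 9 and 53. The dChip values put 2251 of the authors' 2950 probe sets past the threshold. They exist for these picked probe sets alone and were adjusted over them, so that count cannot be compared with those on MAS5 signals. Of the 2251, 706 had passed with MAS5 signals and 58 had the other sign there. Of the 64 named genes past the test all 64 kept their sign on dChip values, and in 28 the log2 change was smaller by over 1.5 times. The cause of these differences was not tested except where stated.

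Of 116 named genes 64 passed the test, and none of these changed sign under the 14 alternatives in which they were tested. Filters, variance models and removal of _s_at, _x_at and _a_at probe sets leave a log2 change as it was, so signs could not change there. Without a low filter 44 lost the call and without the trend 64, against 16 at most otherwise. Among these 116 and the fixed lists, the values that reversed belong to results not past the test; of all 500 named genes past it 10 had the other sign on dChip values, NNT among them (0.80 against -0.27). For the TGF-beta target list they were adjusted p values of 0.181 with fry, 0.980 without a low filter, 0.792 without the trend and 0.406 without _s_at, _x_at and _a_at probe sets, all upward; for heat shock, 0.750 and 0.990 without resveratrol replicates 1 and 2 and 0.985 without those probe sets, all downward. ACACA had log2 changes from -0.177 to 0.0807 with each resveratrol array left out, and on dChip values ACVR1B had 0.0844 and ITGB6 -0.0412. The cause was not tested.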

Other observations

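The tests of probe sets that match several transcripts, of array scaling, of the choice of listed probe sets, of hybridisation brightness and of RNA degradation were set after the results they measure had been seen, and the genes of the authors' lists were named after their values were seen. Further lists of the authors held changes not yet described. All 8 tested genes of nicotinate and nicotinamide metabolism had positive changes and 4 rose: the NAD synthesis genes NMNAT1 (2.91-fold) and NADSYN1 (1.76-fold), the transhydrogenase NNT (1.74-fold) and NNMT (1.31-fold), with a camera adjusted p of 0.00892 and an adjusted p = 0.369 with an estimated correlation; on dChip values the log2 change was 0.29 for NMNAT1 and -0.27 for NNT, the other sign, with 0.52 for NADSYN1 and 0.20 for NNMT. Among 35 lysosomal genes 11 rose and 4 fell (adjusted p = 0.143), with ARSD 2.49-fold and CTSS 1.99-fold higher (log2 changes of 0.037 and 0.34 on dChip values, and -0.21 for CTNS) and CTNS lower by -0.76 on the log2 scale. All 9 genes listed under positive regulation of apoptosis had negative changes and 3 fell, FAF1, EEF1E1 and IGFBP3, with changes of -0.72, -0.61 and -0.50 (camera adjusted p = 0.0308, and 0.366 with an estimated correlation; EEF1E1 had -0.27 on dChip values). In glutathione peroxidases 4 of 5 rose and GPX4 fell, with a change of -0.32.

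The p53 targets were higher on the resveratrol arrays, with a median log2 change of 0.75. With a resveratrol array standing in for the control the median over the same 16 genes was at most 0.0869 in size. The 7 members measured by probe sets without an _s_at, _x_at or _a_at ending had a median of 0.764. Neither value decides on noise between single arrays or on probe sets that match several transcripts, whatever was predicted of them: all 16 genes are named through probe sets that the authors picked on these same arrays with the control on one side, and such probe sets passed the test more often than others (28.4% against 4.34%). With 1 control array, another difference between the control culture and the treated cultures cannot be told apart from resveratrol.

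The 42 genes of the authors' mRNA processing list had a median change of -0.31. All tested probe sets together had a median of -0.01499, but scaling to a common mean holds that value near 0, and the listed probe sets had a median of -0.23 with 40.8% positive, so that scaling of the arrays cannot be told apart. The 25 members measured by full-length mRNA probe sets had a median of -0.286, all negative. They too were picked by the authors on these arrays, so the value predicted for full-length probe sets does not decide on EST or unspliced sequence; over all listed probe sets the median was -0.18 for full-length mRNA and -0.29 for EST. The list holds 21.5% of the pathway's probe sets on the array, so the authors' choice of probe sets may account for part of the fall and stays open, as do resveratrol and the single control.

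The 18S ribosomal RNA probe sets were 4.64-fold to 7.71-fold brighter on the control array than the resveratrol mean, and 3.90-fold to 12.7-fold with a resveratrol array left out. Spike probe sets were brighter there by 0.187 on the log2 scale. Scaling to a common mean takes out a uniformly brighter scan, from the 18S probe sets as well as from the spikes. The 18S difference that remains after scaling therefore argues against such a scan as its source. The 3′ to 5′ difference of GAPDH was larger by 0.0751, which argues against RNA degradation. By the mean of the 18S probe sets replicate 1 had the most signal of the treated arrays, and it was closest to the control for 31.4% of the changed probe sets and 32.3% of those changed 2-fold by the mean. By the 3′ probe set it was replicate 2, with 35.6% and 34.0%. All these shares lie under the bound set beforehand. The test behind the changed probe sets favours little spread between the treated arrays, so their shares decide little. Those changed 2-fold by the mean were picked by size without that test. Their shares argue against gene changes that follow the ribosomal signal across the treated arrays as the whole cause. More ribosomal RNA in the labelled control material may be the source and was not tested; 28S probe sets differed by 0.75, 0.37 and -0.55. A biological difference from resveratrol stays open too.

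With the control array alone on one side 1821 probe sets passed, and with each resveratrol array alone against the other 3 arrays at most 0 did (limma; 524 to 626 at an unadjusted p under 0.05). There the control sits among the other 3 and adds to their spread, so few calls are expected. With the control left out, each resveratrol array against the other 2 gave 1 to 2 calls (1291 to 1743 at an unadjusted p under 0.05). That is 1 of 4 splits, too few for a share under 0.05. Of 585 genes with several named probe sets tested, 0 had calls in both directions. These probe sets were all picked by the authors on these arrays, and that choice may favour such agreement.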
